A study of Sinorhizobium meliloti 1021 with 31 samples.

How the data were processed

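RNA of synchronized *S. meliloti* cultures was labelled with Cy3 and hybridised to Agilent arrays, per the labels' protocols. Per the file headers, the 24 arrays from 30 to 120 min lie on 3 slides, and replicate n of every group lies on slide n. The 7 arrays at 0 and 15 min lie on slide 4. Those on the first 3 slides were read with Agilent Feature Extraction 10.5.1.1 from scans at 3 µm per pixel, and those on slide 4 with version 10.7.3.1 from scans at 5 µm, per the file headers. The time 0 arrays were extracted with a 2-colour protocol and the others with 1-colour protocols, per the file headers. Each group from 30 to 120 min has the same row and column on all 3 slides. Arrays at 30 and 60 min lie in slide row 1, those at 90 and 120 min in row 2. On slide 4 the time 0 arrays lie in row 1 and the 15 min arrays in row 2. From 15 to 120 min all non-treated arrays lie in columns 1 and 3, and all treated arrays in columns 2 and 4. The deposited scanner files hold intensity values per spot: raw medians, background-subtracted signal and processed signal. The authors also deposited a matrix of log2 values per probe, normalized between arrays. The method of that normalization is not given in the sources used here, beyond limma in the submitters' processing notes. Its 29 columns whose names match a sample each correlated best with their own array (r = 0.9931 to 0.9998) and had medians between 12.48 and 12.51; 2 columns matched no sample and were not used.

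The main values were log2 of the processed signal over the array's 75th percentile, with values under 0.005 of that percentile set to 0.005 of it. For the time 0 arrays the background-subtracted green signal was used, because their processed signal is dye-normalized against a red channel that the labels do not describe. Control spots and spots flagged as non-uniform outliers were left out, saturated spots were kept, and the 2 spots of a probe were averaged. The filter on dim probes (well above background on every array of at least 1 group) kept all 6142 genes, of which 5784 were above background on all arrays. A gene saturated on every array of a group has only a bound there. Folds of such genes are given as "at least", from the mean of the brighter group, with saturated spots at their value, against the mean of the dimmer group.

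Each comparison was a contrast in 1 limma fit (lmFit and eBayes, version 3.58.1 in R 4.3.3) over all 31 arrays and 11 groups. Genes passed at an adjusted p under 0.05 (Benjamini-Hochberg over 6142 genes), and every adjusted p for a gene is limma's. Genes with missing spots were fitted exactly on their remaining arrays. Comparisons, main settings and most alternatives were fixed before the data were examined. Named genes are those past the threshold with the largest log2 fold change on each side, for NCR247 comparisons with the same sign in every same-numbered pair. The rule allowed up to 5 or 10 per side; 2 per side are printed because no file used here pairs the identifiers with names.

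The 20 gene lists fixed beforehand use gene symbols. The reference table used here is of another organism, *Ensifer adhaerens*, and holds none of the 6142 identifiers, so the lists had 0 measured members and were not tested. The identifiers were grouped by prefix in their place and tested with limma's camera, with a preset correlation of 0.01 and again with an estimated one. This grouping was chosen after the data were seen.

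Whether replicate numbers pair treated and non-treated arrays was checked from the correlation of their deviations from the group means. It was over 0.1 in 11 of 12 pairs from 30 to 120 min, between 0.0657 (replicate 3 at 60 min) and 0.803, and the numbers equal the slides. Within each slide, between 99.5% and 100% of the genes called at a time from 30 to 120 min moved in the called direction, which is no separate support, as they were called from the same arrays. With the replicate number as a block, the counts were 135, 759, 2235, 2674 and 1933 at 15, 30, 60, 90 and 120 min. No 2 arrays of a group held the same values: the smallest median absolute log2 difference was 0.129. Whether replicates came from separate days is not given in the sources used here, so p values measure the spread between these samples.

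The fit was tested on simulated data made from the real group means and residual spreads of 6142 genes, with 200 genes changed. There was 1 draw per comparison. The noise was independent between arrays, so deviations shared by same-numbered arrays were not modelled. For the comparison at 15 min, 26% of genes changed 1.5-fold and 94% of those changed 4-fold were recovered, with 6.76% of the calls false, above the threshold of 5%. At 30 min these shares were 44% and 98%, with 4.17% of the calls false. For the difference of effects between 30 and 120 min they were 14% and 92%, with 0.8% false. For the average over 30 to 120 min 5.03% of the calls were false. Shares of false calls from 1 draw are imprecise: the 6.76% at 15 min was 10 of 148 calls.

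Alternatives were normexp background correction, quantile normalization, the array median as scaling point, a floor of 0.02, only probes above background on all arrays, only the compared groups in the fit, the deposited matrix, a replicate block, the dye-normalized time 0 signal, and leaving out each array and each replicate number. Added after seeing the data were leaving out genes with saturated spots, a replicate block shared by 0 and 15 min, and the comparison of treated cells at 120 and 30 min.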

Results

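Gene expression was measured by the Cy3 signal of 31 microarrays of *Sinorhizobium meliloti*, the soil bacterium that fixes nitrogen inside the root nodules of alfalfa and related legumes. Synchronized cultures grew for 40 min before the start of sampling. They then received 4 µM NCR247 or nothing. NCR247 is a nodule-specific cysteine-rich peptide, one of a family of host plant peptides delivered to the bacteria inside nodule cells. Non-treated and treated cells were each sampled at 15, 30, 60, 90 and 120 min, and cells were also sampled at time 0. Time 0 had 3 arrays, both groups at 15 min had 2 arrays each, and the 8 groups from 30 to 120 min had 3 arrays each. The titles in the labels number the arrays of a group as biological replicates.

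Each array carried 6142 gene identifiers, each with a single probe printed in 2 spots. Signal was high: between 94.5% and 99.97% of spots per array stood well above background, and the 75th percentile of the processed signal lay between 9813 and 36405. Between 2.65% and 13.8% of spots per array were saturated, so that the largest changes of the brightest genes are underestimated. Arrays of one group correlated at r = 0.954 to 0.992 across genes, leaving out time 0. At time 0, replicates 2 and 3 correlated at 0.995, and replicate 1 correlated with them at 0.935 and 0.929. The number of arrays limits the precision of each value. No file used here pairs the identifiers with gene names, so at most 2 identifiers that rose and 2 that fell are given for each comparison. The identifier prefixes SMa, SMb and SMc belong, in the naming scheme of the strain's genome, to the pSymA megaplasmid, the pSymB megaplasmid and the chromosome. They cover 1284, 1561 and 3297 identifiers. Levels are log2 signal relative to the array's 75th percentile.

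What NCR247 changed in synchronized cells, and when, was addressed by comparing treated with non-treated cells at each time. Treated arrays lay only in slide columns 2 and 4, and non-treated arrays from 15 min on only in columns 1 and 3. An effect of the position on the slide therefore cannot be told apart from that of NCR247 by the layout. In the comparisons of treated with non-treated cells, a rise or a fall is the treated against the non-treated level, not a change over time. At 15 min the response was already visible in 117 genes, 101 higher and 16 lower in treated cells. The largest rises were those of SMb20837 (log2 fold change 3.13, SE 0.51, adjusted p = 0.000992, n = 2 per group) and SMc02388 (3.04, SE 0.58, adjusted p = 0.0037). SMc02388 had a saturated spot on 1 of the 2 treated arrays. SMb20837 lay at -1.68 ± 1.08 in non-treated and at 1.45 ± 0.14 in treated cells (SD, n = 2). The largest falls were those of SMc03046 (-1.80, SE 0.27, adjusted p = 0.000473) and SMc02582 (-1.44, SE 0.31, adjusted p = 0.0121). All 117 genes moved the same way in both same-numbered pairs, the pairs from which they were called. This early count rests on the spread estimated from all groups: with the 4 arrays of 15 min fitted alone, limma called 0 genes, with 344 at an unadjusted p under 0.05. Without replicate 2 of both groups it also called 0 genes, with 143 at an unadjusted p under 0.05, and without replicate 1 it called 62.

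At 30 min, 620 genes differed, 405 higher and 215 lower in treated cells. SMc01657 rose from a level of -5.06 ± 0.11 in non-treated to -0.25 ± 0.22 in treated cells (SD, n = 3), a log2 fold change of 4.80 (SE 0.29, adjusted p = 1.12e-10). SMc01514 rose by 4.51 (SE 0.30, adjusted p = 3.68e-10). SMc03028 fell by 2.75 on the log2 scale (SE 0.32, adjusted p = 8.02e-07) and SMc03046 fell by 2.62 (SE 0.22, adjusted p = 8.23e-09). Of the 101 genes that were higher at 15 min, 100 were also higher at 30 min, against 6.66 expected for independent lists, and all 16 that were lower were lower again. Leaving out 1 replicate number from both groups gave 362, 366 or 377 genes.

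At 60 min, 1998 genes differed, 1145 higher and 853 lower. SMc01657 and SMc01514 again rose most, by 5.34 (SE 0.29, adjusted p = 4.56e-13) and 5.18 (SE 0.30, adjusted p = 1.62e-12). The largest falls were those of SMc03027 and SMc03028. SMc03027 changed by -6.31 (SE 0.29) and SMc03028 by -6.30 (SE 0.32), from levels of 0.71 ± 0.29 and 1.28 ± 0.35 in non-treated cells to -5.61 ± 0.65 and -5.02 ± 0.59 in treated cells (SD, n = 3). The balance of rises and falls depended on the scaling: 57.3% of the changed genes were higher in treated cells with the 75th percentile as scaling point, 42.6% with the array median, and 50% in the deposited matrix. The median of all genes was -0.01 with the first and -0.13 with the second. Without replicate 3, 1325 genes were called.

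At 90 min the number of changed genes was 2450, with 1487 higher and 963 lower. SMc00809 rose by 4.55 (SE 0.49) and SMc01514 by 4.45 (SE 0.30). SMc00809 had a saturated spot on 1 of the 3 treated arrays. SMc03010 was lower in treated cells by 5.22 on the log2 scale (SE 0.22) and SMc03005 by 5.11 (SE 0.20). From 30 to 90 min SMc03010 went from -2.55 ± 0.22 to 0.24 ± 0.44 in non-treated cells (SD, n = 3). In treated cells it went from -3.89 ± 0.09 to -4.98 ± 0.27 (SD, n = 3). SMc03005 had a saturated spot on 2 of the 3 non-treated arrays at this time. The treated arrays of this time were unlike one another for some genes: SMa1118, one of the identifiers that rose over time in non-treated cells, lay at -1.63 ± 3.24 (SD, n = 3).

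At 120 min, 1682 genes differed, 1161 higher and 521 lower. SMc02388 rose by 5.07 (SE 0.47) and SMc00252 by 4.99 (SE 0.42), each with a saturated spot on 1 of the 3 treated arrays. SMc00975 stood at 1.16 ± 0.58 in non-treated and at -4.95 ± 0.11 in treated cells (SD, n = 3), a change of -6.11 (SE 0.23, adjusted p = 1.14e-15). It had a saturated spot on 1 of the 3 non-treated arrays. SMc03006 changed by -5.82 (SE 0.24, adjusted p = 5.38e-15) and had a saturated spot on 2 of the 3 non-treated arrays. The share of changed genes that were higher was 69.0% with the 75th percentile, 53.9% with the array median, 57.7% with quantile normalization and 56.9% in the deposited matrix. The median of all genes moved from 0.13 with the first to 0.02 with the second. A fit of only the 6 arrays of this time called 1041 genes.

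**Figure D1:**
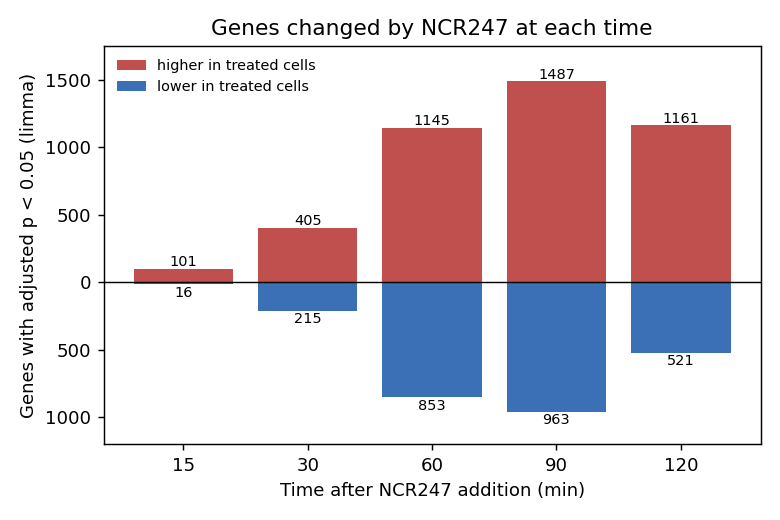
Bars show the number of genes higher (red, upward) and lower (blue, downward) in NCR247-treated than in non-treated cells at each time in min, at an adjusted p under 0.05 by limma. Counts go from 101 higher and 16 lower at 15 min to 1487 higher and 963 lower at 90 min; the split at 60 and 120 min depends on the scaling.

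Averaged over 30 to 120 min, NCR247 changed 3235 of 6142 genes (52.67%), with 1858 higher and 1377 lower. Most of these changes were small: their median size was 0.42 on the log2 scale. By 2-fold or more, 251 genes were higher and 189 lower. Among the genes called at 30, 60, 90 and 120 min the median size was 0.78, 0.68, 0.74 and 0.72. The scaling again set the balance: 57.4% of the changed genes were higher with the 75th percentile and 46.6% with the array median. SMc02388 rose by 4.56 (SE 0.23, adjusted p = 4.23e-14) and SMc00809 by 4.46 (SE 0.24, adjusted p = 1.29e-13). SMc02388 had a saturated spot on 1, 1, 2 and 1 of the 3 treated arrays at 30, 60, 90 and 120 min. SMc00809 had one on 1 treated array at each of 60, 90 and 120 min. SMc03027 and SMc03028 were at least 19.6-fold and at least 18.1-fold lower in treated cells (log2 SE 0.15 and 0.16, adjusted p = 2.57e-17 and 1.06e-16). These are bounds because both had a saturated spot on all 3 non-treated arrays at 90 min. At all 4 times 306 genes were higher and 93 genes were lower, while 51 genes were higher at one of these times and lower at another. Across genes, which are not independent replicates, the NCR247 effects at 30 and 120 min correlated at r = 0.625, and those at 90 and 120 min at 0.855.

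By replicon, 552 of the pSymB identifiers were higher and 230 lower in the averaged comparison. On the chromosome 984 were higher and 800 lower, and on pSymA 322 were higher and 347 lower. In limma's camera test with the preset correlation, the pSymB identifiers ranked higher than the rest (adjusted p = 0.0343), and so they did at 60 min (adjusted p = 0.0215) and at 90 min (adjusted p = 0.038). With an estimated correlation the adjusted p values were 0.523, 0.449 and 0.341. At 90 min the pSymA identifiers ranked lower (adjusted p = 0.00623), with 231 higher and 352 lower, and the adjusted p was 0.221 with an estimated correlation.

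**Figure D2:**
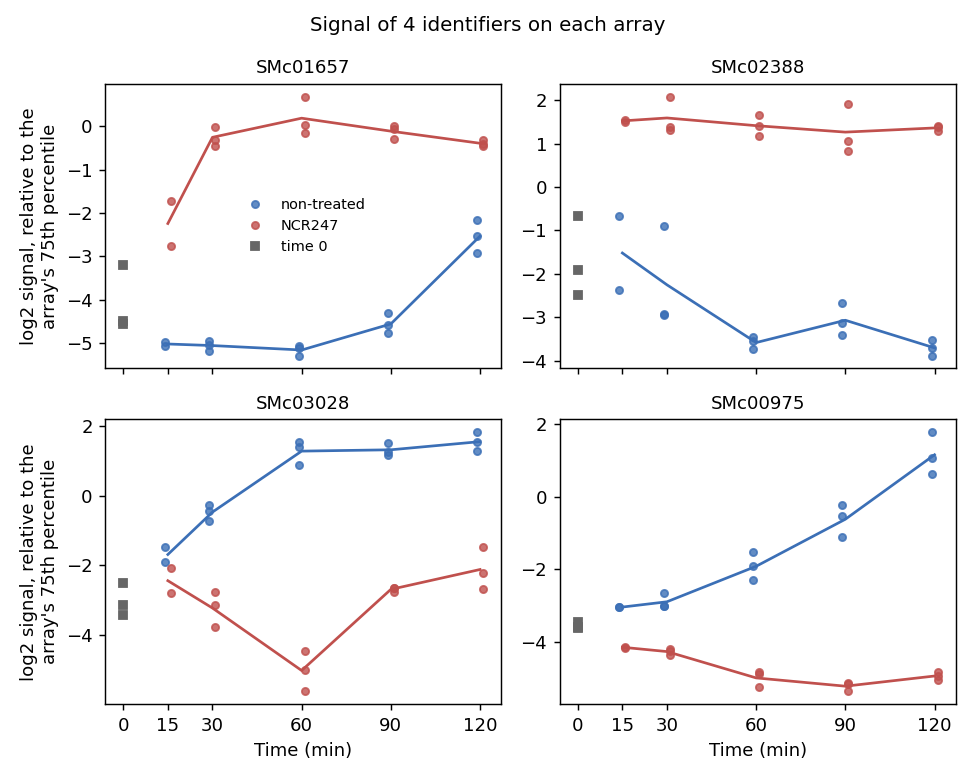
Points show the log2 signal of 4 identifiers on each array, relative to the array's 75th percentile, against time in min, for time 0 (grey squares), non-treated (blue) and NCR247-treated cells (red); lines join group means. SMc00975 reached 1.16 in non-treated and -4.95 in treated cells at 120 min, while SMc01657 stood at -5.06 in non-treated and -0.25 in treated cells at 30 min.

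Whether the response itself changed with time was asked by testing the difference of the NCR247 effects at 120 and 30 min. It differed in 496 genes, more positive at 120 min in 260 and more negative in 236. The effect on SMc00975 went from -1.38 at 30 min to -6.11 at 120 min, a difference of -4.73 (SE 0.32, adjusted p = 5.32e-10). Over that time SMc00975 rose by 4.06 in non-treated cells and changed by -0.675 in treated cells. SMc03008 differed by -4.36 (SE 0.30, adjusted p = 5.32e-10). SMa0185 differed by 2.30 (SE 0.32, adjusted p = 4.56e-05) and SMb20911 by 2.26 (SE 0.55, adjusted p = 0.0103). In non-treated cells SMa0185 went from -1.21 ± 0.16 at 30 min to -3.50 ± 0.21 at 120 min, and in treated cells from -0.83 ± 0.03 to -0.82 ± 0.66 (SD, n = 3). With the array median as scaling point 30.5% of the changed genes were more positive at 120 min, against 52.4% with the 75th percentile. The median of all genes was 0.02 and 0.13. Leaving out replicate 1, 2 or 3 gave 240, 285 or 195 genes.

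The course of expression in synchronized non-treated cells from 30 to 120 min was tested on its own. Expression varied over these 4 times in 3512 genes by limma's F test. Between 30 and 120 min, 1102 genes rose and 1912 fell. SMa1118 and SMa1211 had a saturated spot on all 3 arrays at 120 min. They were at least 262-fold and at least 170-fold higher than at 30 min (log2 SE 0.98 and 0.87, adjusted p = 4.13e-07 and 2.5e-07). Their levels at 30 min were low and scattered, at -6.24 ± 1.38 and -5.63 ± 0.73 (SD, n = 3). These folds are therefore bounds with regard to saturation only, and are themselves imprecise. SMb20938 fell by 4.61 on the log2 scale (SE 0.26, adjusted p = 3.01e-12), with a saturated spot on 1 of the 3 arrays at 30 min, and SMb20939 fell by 4.57 (SE 0.26, adjusted p = 3.25e-12). Of the steps between consecutive times, the one from 60 to 90 min changed 1997 genes, against 552 from 30 to 60 min and 940 from 90 to 120 min. On all 3 slides the 30 and 60 min arrays lay in slide row 1 and the 90 and 120 min arrays in row 2. The step from 60 to 90 min and the change from 30 to 120 min therefore cannot be told apart from a change of slide row. The pSymA identifiers ranked higher at 120 than at 30 min (300 higher and 291 lower, adjusted p = 0.0291 by camera; adjusted p = 0.386 with an estimated correlation).

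The same course was followed in treated cells, a comparison added after the data were seen. Here 2208 genes differed between 30 and 120 min, 1159 higher and 1049 lower at 120 min. With the array median the share that was higher was 34.9%, and with quantile normalization 42.2%, against 52.5% with the 75th percentile, and the median of all genes moved from -0.07 to -0.22 with the array median. The steps changed 737, 413 and 158 genes. The change of slide row between 60 and 90 min was shared by both courses. Of the genes that rose in non-treated cells 787 also rose in treated cells (208 expected for independent lists), and of those that fell 878 also fell (327 expected). The changes of the 2 courses correlated at r = 0.863 across genes.

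Each array from 30 to 120 min was also placed on the non-treated course by the genes that changed by more than 1 on the log2 scale between 30 and 120 min on the non-treated arrays of the other 2 slides, a measure chosen after the data were seen. On this scale 0 is the non-treated array at 30 min and 1 the non-treated array at 120 min of the same slide. Treated cells lay at 0.01 ± 0.03 at 30 min, 0.12 ± 0.05 at 60 min, 0.40 ± 0.14 at 90 min and 0.64 ± 0.02 at 120 min (SD, n = 3). Non-treated cells lay at 0.20 ± 0.01 at 60 min and at 0.77 ± 0.07 at 90 min (SD, n = 3). On genes with no saturated or floored value the means at 60 min were 0.23 in treated and 0.18 in non-treated cells, the other way round. On all course genes, all 3 treated arrays lay under all 3 non-treated arrays at both times. An exact permutation test gave a two-sided p = 0.1 at each, the smallest that 3 against 3 arrays can give. That test moved arrays freely between slides, although each position is scaled to its own slide. It therefore ignores the pairing by slide and decides nothing.

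**Figure D3:**
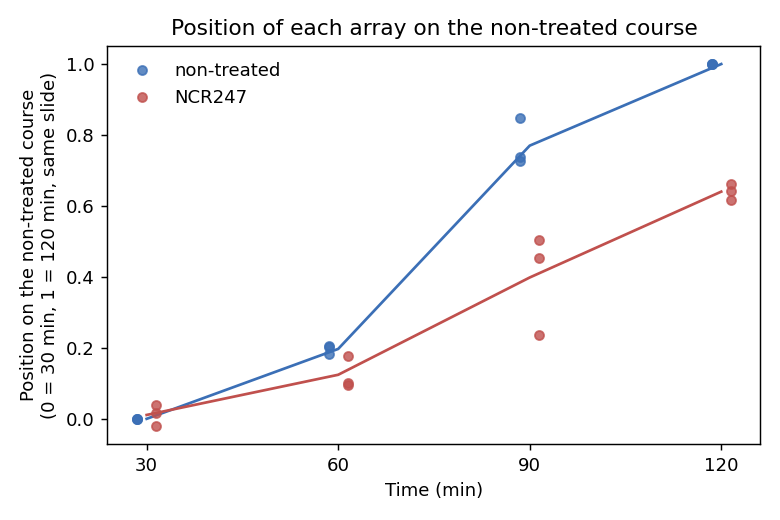
Points show the position of each array from 30 to 120 min on the non-treated course (0 = non-treated array at 30 min, 1 = non-treated array at 120 min, same slide) against time in min; lines join the means of non-treated (blue) and NCR247-treated cells (red). At 120 min the treated arrays lie between 0.62 and 0.66.

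Between 0 and 15 min in non-treated cells, 30 genes differed, 8 higher and 22 lower at 15 min. SMc03014 rose by 1.27 (SE 0.25, adjusted p = 0.0215) and SMc03029 by 1.20 (SE 0.27, adjusted p = 0.0464). SMb20346 fell by 1.43 on the log2 scale (SE 0.18, adjusted p = 0.000395) and SMb20347 fell by 1.36 (SE 0.27, adjusted p = 0.0215). The share that was higher was 26.7% here and 47.6% with quantile normalization, and the count varied with single arrays: 1 gene without replicate 1 at 15 min, 9 without replicate 2 at 15 min, 13 without replicate 1 at time 0, 52 without replicate 2 at time 0 and 4 without replicate 3 at time 0. The time 0 arrays were extracted with another protocol (2-colour) than the 15 min arrays of the same slide and scan. Per the labels each time 0 array came from 1 culture of 5 ml, against 5 pooled samples of 1 ml at 15 min. The time 0 arrays also lay in slide row 1 and the 15 min arrays in row 2. The extraction protocol, the handling of the cultures, the slide row and the time therefore cannot be told apart. With the dye-normalized signal of the time 0 arrays the count was 3334. Same-numbered arrays at 0 and 15 min deviated together. A block shared by 0 and 15 min, added after seeing the data, gave 470 genes. The planned replicate block gave 20 genes, 12 of them also among the 30. It joined no time 0 array to a 15 min array and put the 15 min level at that of replicate 2. So it did not model the shared deviations, and its 20 is no count adjusted for them.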

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

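The NCR247 effect differed between 30 and 120 min, by a test of the difference itself, in 496 genes. Of 100 splits of the 12 arrays within their times, the real one included, 6 gave as many genes. The highest other split gave 1123, more than the real 496, so chance is not excluded by this count. The share varies with the splits drawn: in other draws of 100 it went from slightly lower to well above 0.05. The high counts point to a structure of the samples: all 5 other splits with as many genes keep treated and non-treated arrays apart at 120 min and mix them at 30 min, so they hold the whole effect of NCR247 at 120 min and are no picture of an absent effect. The 79 splits that mix the arrays at both times gave at most 27 genes.

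Among the named identifiers the difference of effects, at 120 min minus 30 min on the log2 scale, was -4.73 for SMc00975, -4.36 for SMc03008, -4.28 for SMc03006, -4.27 for SMc03010 and -3.34 for SMc03005. The value for SMc03005 is a bound, as it had a saturated spot on all 3 non-treated arrays at 120 min, so that the difference was at least this large. SMc00975, SMc03006 and SMc03010 had one on 1, 2 and 1 of these 3 arrays. All 5 identifiers were lower in treated cells at both times, and by more at 120 min. From 30 to 120 min they rose in non-treated cells, by 3.29 (SMc03005, a bound) to 4.06. In treated cells they changed by -0.675 to -0.05 over that time. The difference was -2.66 for SMc01657 and -2.27 for SMc01514. These were higher in treated cells by 4.80 and 4.51 at 30 min and by 2.14 and 2.25 at 120 min. From 30 to 120 min they rose by 2.52 and 2.27 in non-treated cells, and changed by -0.14 and 0.0004 in treated cells. The difference of effects was -1.34 for SMc03027 (adjusted p = 0.0488, the weakest of these), 2.26 for SMb20911 and 2.30 for SMa0185.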

How the results depend on the processing

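Counts of changed genes for the NCR247 comparisons at 30 to 120 min, for their average, for the difference of effects and for the courses from 30 to 120 min stayed within 1.5 times the reported count under every alternative that kept all arrays, except the fit of only the compared groups at 120 min (1041 genes). That fit called 0 genes at 15 min (344 at an unadjusted p under 0.05) and 0 between 0 and 15 min (253), with fewer samples to estimate the spread. The other exceptions concern 0 against 15 min: 17 genes with the array median, 3334 with the dye-normalized time 0 signal, where the median of all genes was -0.53, and 470 with a replicate block shared by 0 and 15 min, which was added after seeing the data; the cause was not tested. The planned replicate block gave 20 genes there, but it held no time 0 array, so this is no count adjusted for shared deviations. It changed no other count by over 1.5 times. Leaving out arrays gave 0 to 87 genes at 15 min (19 without non-treated replicate 2, 65 and 18 without treated replicate 1 and 2, 62 without replicate 1; 0 without replicate 2), 362 to 571 at 30 min, 1325 to 1821 at 60 min, 195 to 514 for the difference of effects, and 1 to 52 between 0 and 15 min. The 36 results for named identifiers kept their direction in all 713 alternatives and lost the threshold in 42. The alternative with no filter on dim probes changes nothing, since the filter removed no gene, and the one with the brightest probe was void with 1 probe per gene. The normexp alternative used median signals, as the files used here have no mean signal, and the deposited matrix was not run for NCR247 at 15 min, whose treated columns were not mapped. Saturation, at up to 13.8% of spots, limits the highest levels; signal over background limits few values.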

Other observations

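Tests chosen after their result was seen are those of a mislabelled array, of a gradient across slide columns, of another point of the time course and of co-transcribed neighbours.

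Genes changed by NCR247 lay in runs of neighbouring identifiers. In the averaged comparison, 115 runs of 5 or more consecutive identifiers changed in one direction, 79 higher and 36 lower, against at most 35 in 200 shuffles within prefixes. The longest run, from SMc03004 to SMc03057, held 54 identifiers, all lower in treated cells, with a median log2 fold change of -3.31. Its median was -0.68 at 15 min, -1.89 at 30 min, -4.40 at 60 min, -3.88 at 90 min and -3.24 at 120 min, while in non-treated cells it rose by 2.28 from 30 to 120 min. Of the 54, 2 at 60 min, 31 at 90 min and 13 at 120 min had a saturated spot on all 3 non-treated arrays, so these medians rest in part on saturated values. The 19 members with no such saturation from 30 to 120 min had medians of -1.38, -3.03, -4.54 and -3.74 at 30, 60, 90 and 120 min, and of 2.71 for the rise in non-treated cells, so the time of the largest median depends on the members used. The longest run of higher identifiers, from SMb20941 to SMb20961, held 21, with a median of 1.41; 8 of them had a saturated spot on every treated array of at least 1 time from 30 to 120 min, and the other 13 also gave 1.41. These runs were chosen after their values were seen.

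Of the changed genes, 49.1% had a next identifier changed in the same direction, against 26.1% to 28.9% in 95% of 1000 shuffles. At 20 steps apart the share was 30.0%. This was lower, but still above the 26.2% to 28.9% of shuffles there and their highest value of 29.8%. Co-transcribed neighbours may account for the share at the next identifier, as a hypothesis, since no operon annotation was used here. The excess at 20 steps was not tested further. Placement on the array could be another source, but for spots 1 row apart 27.3% of changed genes had a neighbour changed in the same direction, within the 25.8% to 28.0% of shuffles, which argues against it as the whole cause. A first version of that test, on spots 2 rows apart, gave 28.0%, at the edge of its range of 25.9% to 28.0%.

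Treated arrays lay behind non-treated arrays on the non-treated course, at 0.64 ± 0.02 at 120 min (SD, n = 3). The course genes were picked for their change in non-treated cells, whose arrays at 120 min are set to 1. A treated course that merely differs can also lie under 1 on such genes. No placement on genes picked in treated cells was run. On genes with no saturated or floored value the position was 0.668 at 120 min, so saturation does not account for the gap there. On these genes treated cells at 60 min lay at 0.23 and non-treated cells at 0.18, the other way round than on all course genes, so the gap at 60 min depends on the genes used. On course genes with an NCR247 effect under 0.2 at 30 min, 6 of the 6 treated arrays at 90 and 120 min still lay under every non-treated array of their time. At 120 min the non-treated arrays are set to 1 and have no spread, so only the arrays at 90 min face measured values. There treated arrays lay at 0.177 to 0.624 and non-treated arrays at 0.726 to 0.88. At 90 min this argues against early NCR247-responsive genes as the whole cause. A mislabelled array at 90 min would put 1 array behind, and 3 of 3 were. A slower or a weaker course in treated cells may each give this pattern, and they were not told apart by a test. An effect of the slide column, which differed between treated and non-treated arrays, cannot be told apart from these by the layout.

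Same-numbered arrays at 0 and 15 min deviated together, with correlations across genes of 0.603 to 0.855. After a loess fit on mean signal the lowest was 0.588, which argues against a smooth trend with mean signal as the whole cause. Replicate 1 was the brightest array of each group. Its 75th percentile was 16647 at time 0, against 13476 and 11151. At 15 min it was 26206 against 15180 in non-treated and 20923 against 14696 in treated cells. Other effects of brightness, such as saturation, were not tested. The 0 and 15 min arrays were placed on the course between the means of the non-treated arrays at 30 and at 120 min of the other 3 slides. Along the slide columns, the step from time 0 replicate 2 to 3 was 0.0287 of the step from replicate 1 to 2, which argues against an even gradient; other column effects were not tested. In 3 of 3 groups replicate 1 lay earlier on the course than replicate 2, by 0.18, 0.14 and 0.13. This follows from the shared deviations themselves, so it does not decide whether replicate 1 stood at another point of the time course, and the cause stays open.

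Other splits of the same arrays were counted for each comparison with at least 3 arrays per group. For the averaged comparison 1 of 100 splits, the real one, gave as many genes (3235, with 987 as the highest other). For the F test over time in non-treated cells it was also 1 of 100 (3512, with 1772 as the highest other). This share is under 0.05 for both, but it rests on the 100 splits drawn. For 3 against 3 arrays the 10 splits are too few for a share under 0.05, and in each the real split was the 1 highest. At 30, 60, 90 and 120 min the real counts were 620, 1998, 2450 and 1682, and the highest other split gave 0 at 30 and at 60 min, 145 at 120 min, and fewer than that at 90 min. Among the 4 splits that part all 3 same-numbered pairs, the highest other was 0 at each of these times. Between 30 and 120 min the counts were 3014 (highest other 1) in non-treated and 2208 (highest other 2) in treated cells.

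The labels do not describe the red channel of the time 0 arrays. It showed signal above background in 4.88%, 3.31% and 5.52% of gene spots. For negative control spots the shares were 1.3%, 3.9% and 2.6% (Fisher's exact test, two-sided p = 0.186, 0.743 and 0.445). Median red signal was 66.5, 71 and 65 on gene spots and 64, 68 and 63 on negative control spots. Red and green signal correlated (Spearman 0.507, 0.339 and 0.426). With 77 negative control spots per array, the test cannot show that the red channel was empty.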
